A study of Dugesia japonica with 2 samples.

How the data were processed

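Heads of intact Dugesia japonica and head blastemas labelled 5 dpa were each pooled, dissociated to single cells and sequenced as 3' droplet libraries (10x Genomics Chromium, per the labels' protocols), 1 library per group. The deposited files hold raw UMI counts per feature and cell barcode, made with Cell Ranger 7.1.0 per the file headers. Seurat is also named in the submitters' processing notes, and its role is not given in the sources used here. The genome build, the annotation and the rule by which barcodes were chosen are likewise not given in the sources used here. Both libraries list the same 38792 identifiers, of which 28999 begin with DJKW and 9793 with Maker, and each holds exactly 8000 barcodes. The lowest barcode has 1768 UMIs in the intact and 1627 in the 5 dpa library. The libraries share 11 barcodes.

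The files give each identifier a second time in place of a gene name. The 326 entries of 22 lists of cell type markers and gene groups, fixed before the data were examined, therefore matched 0 features. No cluster could be named as a cell type, and the comparisons of gene lists, of the share of cells with a UMI of a list gene and of the gene in the series title gave no value. At most 2 identifiers that are higher and 2 that are lower are printed per comparison, which was also fixed beforehand.

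Barcodes with at least 200 features and at least 500 UMIs were kept. This removed 7 intact barcodes (0.0875%) and 953 5 dpa barcodes (11.9%), and left 7993 cells with 30934858 UMIs and 7047 cells with 24118001 UMIs. Scrublet, run per library through scanpy 1.11.5, made 0 calls in both, which was taken as a caller that had not worked; no doublets were removed, and cells of very high UMIs were left out in an added alternative. All kept cells were clustered together with no correction between libraries. Features found in at least 10 cells were scaled to 10000 UMIs per cell and log transformed, 2000 variable features were chosen with the library as batch, and 30 principal components, 15 exact nearest neighbours and Leiden clustering at resolution 1 (igraph 0.11.9) were used. The weights of the neighbour graph had not been fixed. A first look at the clusters used another weighting, and the Jaccard overlap of neighbour lists (minimum 0.0667) was then taken because it gave identical results on repetition.

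The following rules were set after the data were seen. A cluster was called separated if its 5 leading features, by fold over all other cells among features with a UMI in at least 25% of its cells, were all at least 10-fold higher. The sizes of separated clusters were compared if both libraries gave at least 20 cells and the leading features' median log2 ratio between libraries lay within 1 of that of all features in the cluster. Of 30 separated clusters, 23 met this; in 4 the leading features differed between libraries and 3 had too few cells in 1 library. The alternatives that leave out the 3 most abundant features, keep only cells of separated clusters, ask for 1000 UMIs outside the abundant features or drop the 5% of cells with most UMIs were also added then.

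With 1 library per group no test was possible. UMIs of all kept cells were summed per library, divided by the library total and compared as CPM and log2 ratios, with exact Poisson intervals. Shares have exact Clopper-Pearson intervals, and a share of 0 is given with the limit of 3 cells of the total, which is one-sided and lies below the upper end of the two-sided interval. Differences in median UMIs per cell within a cluster have bootstrap intervals (20000 draws of cells), 95% over all clusters together. A sum under 3 UMIs was set to 3 in a ratio. Features with at least 100 UMIs over both libraries and at least 50 CPM in 1 of them were considered. The named features were the largest upward and downward log2 ratios with the same sign at equal composition, a rule fixed beforehand. At equal composition, each feature's CPM per cluster was averaged with the mean of the cluster's shares in both libraries as weight. Within clusters with at least 50 cells per library the same sums were compared, asking for at least 100 CPM. Features per cell and shares of cells with a UMI were also taken after thinning each cell to 1000 UMIs.

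Other settings, chosen before the data were examined, were no filter on barcodes, a minimum of 1000 UMIs, a median-of-ratios scale, the mean of CPM per cell, a total without the 50 most abundant features, doublet calls kept, Leiden resolutions 0.5 and 2, log values centred per library, clustering of thinned cells and thinning to 500 UMIs. A cluster was followed into another clustering by its best overlap, with a minimum Jaccard index of 0.3, so that a matching cluster can be a part of it or a wider group. A value under another setting was taken to have stayed if a count lay within 1.5 times the reported one, a ratio of shares of cells within the 95% limits of the reported ratio, a log2 ratio within 1, and a ratio of features per cell or of shares of UMIs within 10%. The comparison of sums was tested on simulated data of the pooled comparison with 200 features changed 4-fold. Of these, 184 passed the filter and all 184 were recovered. Among the 2915 considered features 0 unchanged ones went beyond 2-fold, and 94.9% of the intervals of the intact sums held the true value. The simulated sums had the Poisson error that the intervals assume and no spread between cells. They therefore check the computation only and say nothing about features whose UMIs lie in few cells. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.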

Results

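Single-cell transcriptomes of heads of the freshwater planarian Dugesia japonica, a flatworm that regrows a head after amputation, were compared between intact animals and animals with a regenerating head. The intact library was made from 50 pooled heads. The other library, labelled 5 dpa and described as head blastema (the new tissue that forms at a wound), was made from 90 pooled heads. Each group had 1 library, so no difference between groups has a replicate check, no test was run, and the 95% intervals of sums (exact Poisson) and shares (exact binomial) cover counting error only. The labels place both collections in 1 experiment and call the animals wild type; no sample with the gene in the series title perturbed was analysed here. The intact library held 30950339 unique molecular identifiers (UMIs) and the 5 dpa library 26362503, each over exactly 8000 cell barcodes. The files do not pair their 38792 feature identifiers with gene names, so features are given by identifier and clusters of cells by number, and the known function of a feature could not be stated.

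The first question was how the cells of the libraries differed in RNA content. Cells of the 5 dpa library carried fewer features and gave a larger share of their UMIs to 3 very abundant features. Among kept cells (7993 intact and 7047 at 5 dpa), the median was 3059 UMIs and 1308 features per intact cell, against 2663 UMIs and 733 features per cell at 5 dpa. With every cell thinned to 1000 UMIs, which left out no cell, the medians were 560 and 347 features. DJKW.19663 took 27.7% of all UMIs in intact heads and 37.9% at 5 dpa, DJKW.1695 took 2.92% and 6.05%, and Maker00013858 took 1.70% and 2.43%. Together they made up a median of 31.4% of the UMIs of an intact cell and 56.6% of those of a 5 dpa cell. When cells were thinned to 500 UMIs outside these 3 features, which left out 262 intact and 1150 5 dpa cells, the medians were 426 and 398 features, a ratio of 0.93 in place of 0.62.

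The larger shares were also seen cluster by cluster. In the 23 well separated clusters with at least 50 cells from each library, the share of DJKW.1695 was higher at 5 dpa in 23, with a median log2 ratio of 1.01 and a range of 0.59 to 1.92. Its UMIs per cell were higher in all 23 by an amount similar in most of them (quartiles 84.9 and 100.4 UMIs), so that UMIs from free RNA are not fully set apart from expression. The share of DJKW.19663 was higher in 22, with a median log2 ratio of 0.42 (range -0.14 to 1.41), and that of Maker00013858 in 21, with a median of 0.56 (range -0.08 to 1.10); the UMIs of Maker00013858 per cell were higher in 17 and lower in 6, with quartiles of the difference of 1.12 and 29.7. Over cells with at least 1000 UMIs outside the 3 features, a subset chosen after seeing the data, the share of DJKW.19663 was 1.13 times that of intact heads, against 1.37 times over all kept cells. This subset leaves out cells with a large share of the 3 features by its own rule, and held 6611 intact and 3608 5 dpa cells.

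**Figure D1:**
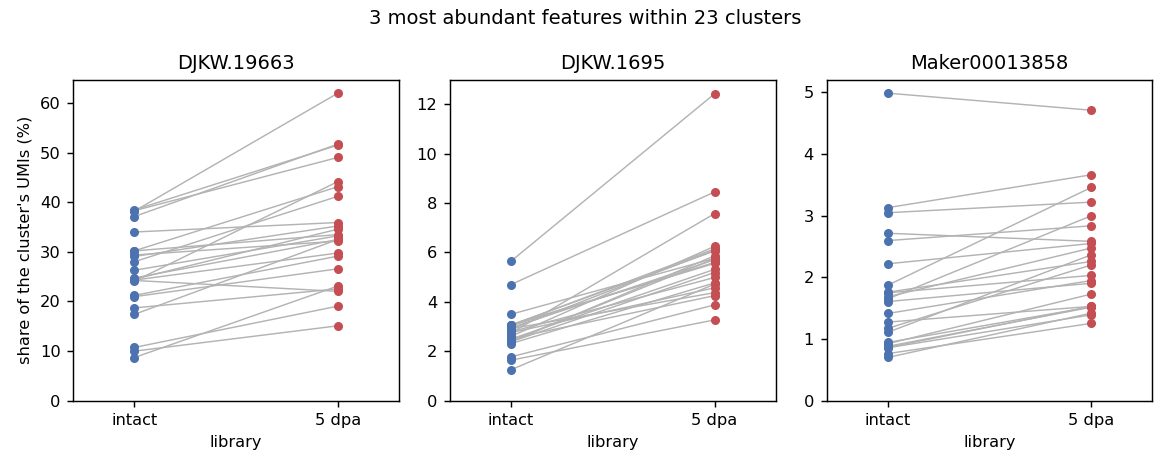
Share of a cluster's UMIs (%, vertical axis) taken by each of the 3 most abundant features in the intact and the 5 dpa library (horizontal axis). Each point is 1 of 23 separated clusters and each line joins the same cluster in both libraries; the share was higher at 5 dpa in 22 clusters for DJKW.19663, in 23 for DJKW.1695 and in 21 for Maker00013858.

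The second question was which groups of cells took a different share of the head at 5 dpa. Of 36 clusters of the jointly clustered cells, 30 were separated by strong leading features and 23 of those could be compared in size. Cluster 17, led by DJKW.14377 and DJKW.22299, made up 0.93% of intact cells (74 cells, interval 0.73% to 1.16%) and 3.86% of 5 dpa cells (272 cells, 3.42% to 4.34%), a 4.17-fold larger share. Cluster 30, led by DJKW.5147 and DJKW.21926, went from 0.40% (32 cells, 0.27% to 0.56%) to 1.33% (94 cells, 1.08% to 1.63%). Cluster 1, the largest, led by DJKW.25550 and DJKW.22459, made up 15.9% of intact cells (1272 cells, 15.1% to 16.7%) and 3.68% of 5 dpa cells (259 cells, 3.25% to 4.14%), a 4.33-fold smaller share.

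A smaller share at 5 dpa was also found for cluster 19, led by DJKW.16556 and DJKW.23091, at 2.85% (2.50% to 3.24%) and 0.68% (0.50% to 0.90%). Cluster 25, led by DJKW.23462 and DJKW.5964, stood at 2.19% (1.88% to 2.53%) and 0.75% (0.56% to 0.98%), and cluster 12, led by DJKW.12285 and DJKW.12002, at 3.6% (3.21% to 4.04%) and 1.43% (1.17% to 1.74%). The other 17 compared clusters differed by less than 2-fold. Among these were clusters 8 and 13, which held cells rich in UMIs (medians of 5887 and 7719.5 UMIs per cell). Their shares were 1.46-fold and 1.67-fold larger at 5 dpa. Over cells with at least 1000 UMIs outside the 3 abundant features the ratios of the matching clusters were 2.06 and 3.09. The latter was for a wider group of 215 intact and 362 5 dpa cells than cluster 13 (157 and 231). This filter kept 6611 intact and 3608 5 dpa cells in all. The match of cluster 8 held 301 and 338 cells, against 281 and 362 before. The smaller 5 dpa total thus raises the ratios of UMI-rich clusters by the rule of the filter. Cluster 8 was led by Maker00021538 and DJKW.3667, and cluster 13 by DJKW.6165 and Maker00004837.

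The 6 clusters without strong leading features held 18.8% of intact cells (18.0% to 19.7%) and 34.7% of 5 dpa cells (33.6% to 35.8%). In them the 3 abundant features made up a median of 60.6% and 70.2% of a cell's UMIs, against 27.4% and 44.6% in the separated clusters. With the cells of separated clusters as denominator, cluster 17 was 5.18-fold, cluster 30 4.14-fold and cluster 13 2.07-fold larger at 5 dpa, and clusters 1, 12, 19 and 25 stayed at least 2-fold smaller. Several shares depended on the clustering and on the cells entered. The ratio of 5 dpa to intact for cluster 1 ranged from 0.039 at a finer resolution, where the matching cluster was a part of it (640 intact and 22 5 dpa cells), to 0.44 over cells with at least 1000 UMIs outside the 3 abundant features. That of cluster 30 was 1.60 with cells thinned to 1000 UMIs, and no matching cluster was found at a coarser resolution or without the 5% of cells with most UMIs. Cluster 22, within 2-fold over all kept cells (ratio 1.26), was at 0.20 (103 intact and 11 5 dpa cells), and cluster 33 (1.11) at 0.31 (36 and 6 cells), over cells with at least 1000 UMIs outside the abundant features. In those cells clusters 12 and 25 were at 0.51 and 0.53, within 2-fold. That filter leaves out cells rich in the 3 features and more 5 dpa than intact cells, so ratios under it follow its rule in part. At the finer resolution clusters 11 and 15 were at 0.37 and 2.42, against 0.70 and 1.57. In cluster 17 the cells differed in depth between the libraries, with medians of 5583.5 UMIs in intact heads and 2448 at 5 dpa.

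**Figure D2:**
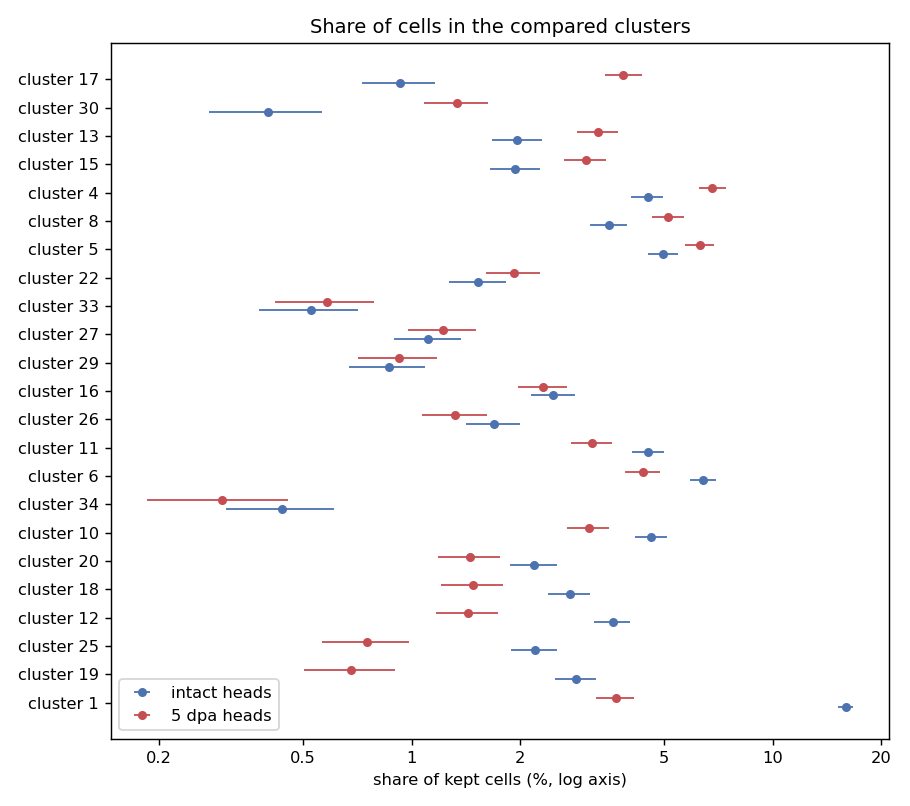
Share of kept cells (%, logarithmic horizontal axis) in each of the 23 compared clusters (vertical axis) for intact heads (blue) and 5 dpa heads (red), with exact 95% binomial intervals that cover counting error only. Clusters are ordered by the ratio of 5 dpa to intact: cluster 17 (0.93% and 3.86%) and cluster 30 (0.40% and 1.33%) stand at the top, and cluster 1 (15.9% and 3.68%) at the bottom.

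The third question was which features differed in abundance between the heads as a whole. Of the features ranked by size under a rule fixed beforehand, 2 that were higher and 2 that were lower are named. DJKW.28764 was at 1.81 CPM (UMIs scaled to the library total; 56 UMIs, interval 1.37 to 2.35) in intact heads and 56.6 CPM (1366 UMIs, 53.7 to 59.7) at 5 dpa, a log2 ratio of 4.97. Cluster 17 held 76.4% of its UMIs, and within this cluster it stood at 47.4 and 974 CPM. It had a UMI in 20.3% of the intact cells of cluster 17 (11.8% to 31.2%) and in 54.8% of the 5 dpa cells (48.7% to 60.8%), against 0.29% and 3.66% of cells outside the cluster, whose median depths were 3051 and 2672 UMIs. Thinned to 1000 UMIs, 1.35% of the intact (0.034% to 7.30%) and 33.5% of the 5 dpa (27.9% to 39.4%) cells of cluster 17 had a UMI. Outside cluster 17 low shares at 5 dpa were spread over most clusters, such as 5.41% in cluster 1 and 3.96% in cluster 12, with 12.9% in cluster 16. There, free RNA in the droplets is not set apart from expression.

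DJKW.3416 was at 1.81 CPM (56 UMIs, interval 1.37 to 2.35) in intact heads and 53 CPM (1279 UMIs, 50.2 to 56.0) at 5 dpa, a log2 ratio of 4.87. It was spread over the clusters. It had a UMI in 0.69% of intact cells (0.52% to 0.89%) and in 15.4% of 5 dpa cells (14.5% to 16.2%), and in the thinned cells in 0.15% and 6.56%. In the 23 separated clusters with at least 50 cells per library this share lay between 9.62% and 19.6% at 5 dpa, against 0 to 2.25% in intact heads. At a level this alike in the clusters, UMIs from free RNA in the droplets are not set apart from expression.

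Maker00018099 was at 103 CPM (3177 UMIs, interval 99.2 to 106) in intact heads and 0.50 CPM (12 UMIs, 0.26 to 0.87) at 5 dpa, a log2 ratio of -7.69. Cluster 33 held 93.1% of its UMIs and had 42 intact and 41 5 dpa cells, in which 45.2% (29.8% to 61.3%) and 17.1% (7.15% to 32.1%) had a UMI. In cluster 33 it stood at 14015 CPM in intact heads and 78.8 CPM at 5 dpa. The 10 cells with most UMIs of it held 92.4% of its intact UMIs, so that few cells set the value; without the 5% of cells with most UMIs the log2 ratio was -5.98. Outside the cluster, 2.39% of intact cells (2.07% to 2.75%) and 0.043% of 5 dpa cells (0.0088% to 0.13%) had a UMI, at median depths of 3058 and 2670.5 UMIs; in cells thinned to 1000 UMIs the shares within the cluster were 38.1% and 9.76%. DJKW.5991 was at 91.8 CPM (2839 UMIs, 88.4 to 95.2) and 0.79 CPM (19 UMIs, 0.47 to 1.23), a log2 ratio of -6.86. Cluster 21 held 83.5% of its UMIs. In this cluster it stood at 3191 and 43.0 CPM, 36.2% of intact (28.8% to 44.1%) and 4.46% of 5 dpa cells (1.47% to 10.1%) had a UMI, and in thinned cells 28.2% and 2.68%. Outside cluster 21 the shares were 4.15% and 0.014%, at median depths of 3043.5 and 2650 UMIs. The 10 cells richest in DJKW.5991 held 70.4% of its intact UMIs. In intact heads the low shares outside clusters 33 and 21 were spread over most clusters (for Maker00018099, 0.61% to 4.44% in the 23 separated clusters with at least 50 cells per library). Free RNA in the droplets is therefore not set apart from expression outside these 2 clusters.

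**Figure D3:**
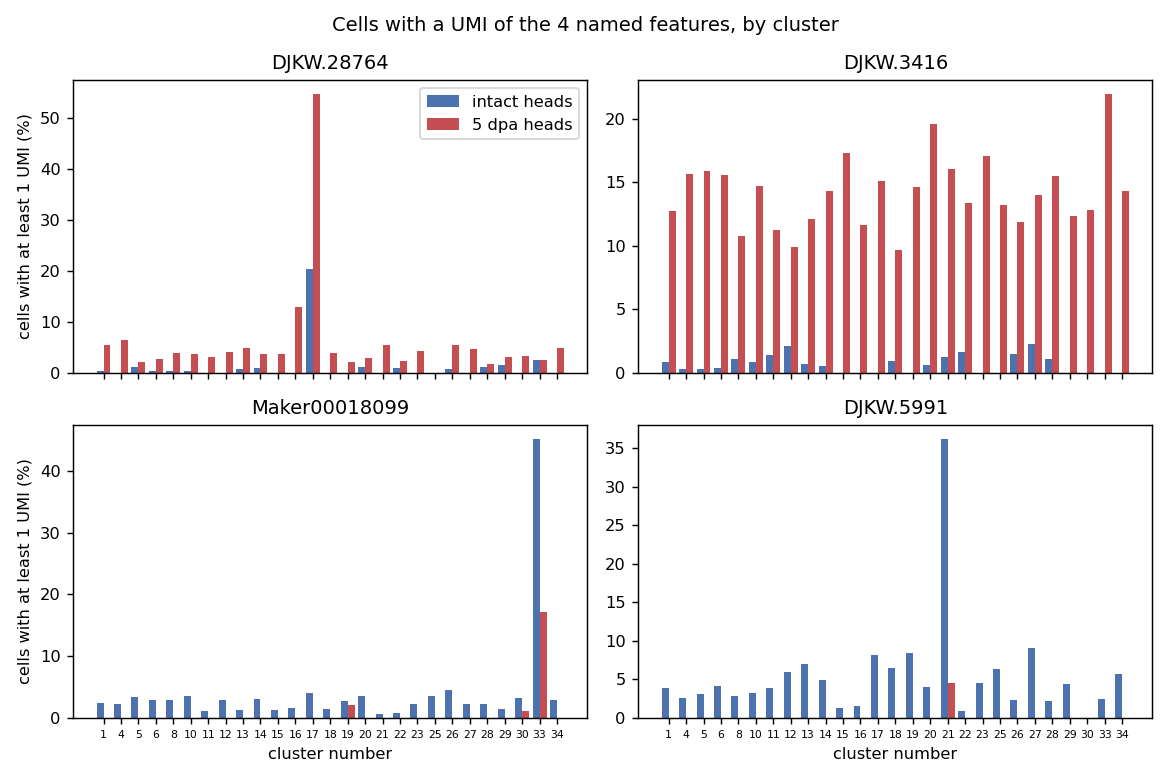
Share of cells with at least 1 UMI (%, vertical axis, without thinning) of the 4 named features in each separated cluster with at least 20 cells per library (horizontal axis, cluster number) for intact (blue) and 5 dpa heads (red). DJKW.28764 peaks in cluster 17 (20.3% and 54.8%), DJKW.3416 is spread over the clusters at 5 dpa, Maker00018099 peaks in cluster 33 (45.2% and 17.1%) and DJKW.5991 in cluster 21 (36.2% and 4.46%).

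Over all 3523 features with enough UMIs to be considered, 41 were at least 2-fold higher and 899 at least 2-fold lower at 5 dpa, as a description of these 2 libraries. This split followed the scale. The median log2 ratio of all considered features was -0.61. With the 3 abundant features left out of the totals, the median was -0.27, a shift of 0.34, and 138 features were at least 2-fold higher and 371 lower. On a median-of-ratios scale, which moved the median by 0.50, the counts were 245 and 228. Both changes of scale raised every log2 ratio by 1 fixed amount, so the higher features could only gain in number and the lower ones only lose.

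With both libraries given the same cluster composition, 20 of 3244 considered features were at least 2-fold higher and 245 lower, with a median log2 ratio of -0.51 over all of them. The 4 named features, chosen among those with the same direction at equal composition, stood in intact and 5 dpa heads at 1.98 and 37.0 CPM (DJKW.28764), 2.11 and 55.4 CPM (DJKW.3416), 85.0 and 0.58 CPM (Maker00018099), and 74.4 and 0.84 CPM (DJKW.5991). Of the features beyond 2-fold in the pooled comparison, 15 of the higher and 231 of the lower ones were also beyond 2-fold at equal composition.

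The last question was what differed within a group of cells. Clusters 17 and 12 were picked as examples after the values were seen. In cluster 17, the first 2 features by size that were higher at 5 dpa were DJKW.14802, at 8.17 CPM (5 UMIs) and 483 CPM (524 UMIs), and DJKW.25238, at 4.90 CPM (3 UMIs) and 205 CPM (222 UMIs). They had a UMI in 5.41% and 4.05% of the intact and in 34.6% and 27.6% of the 5 dpa cells of the cluster. Over the whole libraries their log2 ratios were -0.15 and 4.15, so the rise of DJKW.14802 was not seen in the pooled comparison. Lower in the same cluster were DJKW.12486 (216 and 25.8 CPM, with a UMI in 73.0% and 9.56% of cells) and DJKW.12274 (178 and 24.9 CPM, 37.8% and 4.78% of cells); these shares of cells are not at equal depth. In cluster 12, DJKW.1204 was at 396 CPM (381 UMIs) in intact and 3295 CPM (1185 UMIs) in 5 dpa cells. DJKW.9620 was at 127 CPM (122 UMIs) and 5.56 CPM, the latter from 2 UMIs, fewer than the 3 set as the least in a ratio.

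Some features, picked after their values were seen, differed in many clusters alike. A cluster counted as measured with at least 100 UMIs of the feature over both libraries and at least 100 CPM in 1 of them. Clusters could thus enter through the library where the feature was high, and those low in both were left out, which can raise the counts below. UMIs from free RNA were not set apart from expression for these features. DJKW.22964 was at least 2-fold higher at 5 dpa in 16 of the 18 separated clusters where it could be measured and at least 2-fold lower in 1, and stood at 118 CPM (interval 114 to 122) and 332 CPM (325 to 339) over the whole libraries. DJKW.28029 was at least 2-fold higher in 9 of 10 clusters (268 and 596 CPM overall). DJKW.25576 was at least 2-fold lower in 18 of 20 clusters (218 and 70.2 CPM) and DJKW.28857 in 11 of 12 (124 and 44.7 CPM). Of 1010 features measured in at least 10 clusters, 2 were at least 2-fold higher and 7 lower in at least 75% of them. Over the 27 clusters with at least 50 cells per library, a median of 34 features were at least 2-fold higher and 200 lower. With the 3 abundant features left out of the totals, both medians were 73. No minimum number of cells with a UMI was asked for, so these counts include features set by very few cells. In cluster 1, for example, the largest higher ratio was that of DJKW.17173, with 196 UMIs at 5 dpa in 0.39% of 259 cells.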

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

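The tests in this part were chosen, or their bounds completed, after the result was seen. The 5 dpa library held 953 barcodes with fewer than 200 features (11.9% of its barcodes), against 7 (0.0875%) in the intact library. These barcodes entered no comparison other than the setting without a filter on barcodes. They were not poor in UMIs, since no 5 dpa barcode had fewer than 1627, but the 3 most abundant features made up a median of 91.9% of their UMIs (89.9% in the 7 intact barcodes). They stood out as a signal in data outside the main comparisons.

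In the kept cells DJKW.19663 took 27.7% of all UMIs in intact and 37.9% in 5 dpa heads. A larger number of cells in the clusters without strong leading features is argued against as the whole cause, since within separated clusters the median log2 ratio of the share was still 0.42, above 0 in 22 of 23 clusters. Low-content cells within separated clusters are not excluded by this. There the medians were 1493 features per intact cell and 1042 per 5 dpa cell, with 27.4% and 44.6% of UMIs in the 3 features. Free RNA of this feature added alike to every droplet was tested over 20 clusters whose median depth differed by at most 1.25-fold between libraries. No single amount lay in all intervals of the difference in median UMIs per cell (at least 246 more at 5 dpa in cluster 22 and at most 160 more in cluster 2, a gap of 86.5). The gap rested on cluster 2, which is led by DJKW.19663 itself, so that choosing like depth limits the difference there. The next lowest upper bound was 256 in cluster 16, above 246, so the test cannot decide. With the 3 features left out of the clustering, a gap stayed between its clusters 12 (at least 333) and 21 (at most 265). These intervals take cells as the unit and do not cover differences between animals. Open are low-content cells as part or all of the rise and free RNA as part or all of it. A higher level of the feature in some cell groups of regenerating heads is open too, as an untested hypothesis. The ratio of the shares fell from 1.37 to 1.13 over cells with at least 1000 UMIs outside the 3 features, which cannot decide between these. That filter itself leaves out cells in which the 3 features take a large share, and it kept 6611 intact and 3608 5 dpa cells.

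For DJKW.1695 the median number of UMIs per cell was higher in all 20 of these clusters, with quartiles of the difference of 84 and 102. One even amount of free RNA is only narrowly left out as the whole cause, with a gap of 6.0 UMIs between the intervals of clusters 27 and 16, and it stays open for nearly all of the rise. What these features encode is not given by the identifiers.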

How the results depend on the processing

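The settings that concern the 3 abundant features, separated clusters or the cells with most UMIs were chosen after seeing the data, and the cause of a change was not tested unless stated. The features at least 2-fold higher and lower (41 and 899) numbered 245 and 228 on the median-of-ratios scale, 182 and 295 with a total without the 50 most abundant features, and 138 and 371 without the 3 abundant ones. The higher features numbered 117 over cells with at least 1000 UMIs outside the abundant features (deep cells) and 62 over cells of separated clusters. At equal composition, the lower features numbered 151 with clusters at resolution 2, against 245. Within clusters, the medians of 34 higher and 200 lower features both became 73 without the abundant features in the total. The ratio of features per cell of 0.62 became 0.93 when thinning to 500 UMIs outside them. The number of compared clusters at least 2-fold larger at 5 dpa (2) was 1 at resolution 0.5 and 4 in deep cells, where clusters 8 and 13 were at 2.06 and 3.09. Deep cells numbered 6611 intact and 3608 at 5 dpa, so this filter moves ratios of shares by its own rule. The ratio of shares of cluster 1 (0.23) was 0.39 at resolution 0.5, 0.039 at resolution 2 (a match of 640 and 22 cells), 0.285 after centring per library, 0.098 in thinned cells (766 and 66), 0.17 with the abundant features left out of the clustering, 0.44 in deep cells, 0.276 without the 5% of cells with most UMIs and 0.287 with separated cells as denominator. In deep cells, the ratios of clusters 12, 19, 25 and 30 were 0.51, 0.39, 0.53 and 5.67, and those of clusters 22 and 33 were 0.20 and 0.31, so that the 4 clusters at least 2-fold smaller were 1, 19, 22 and 33. At resolution 2, clusters 11, 15, 17 and 19 were at 0.37, 2.42, 3.0 and 0.16. Clusters 13, 17, 20 and 26 were at 2.31, 5.70, 0.48 and 0.49 without the 5% of cells with most UMIs, and with the abundant features left out clusters 4, 19 and 30 were at 2.17, 0.40 and 2.08. Cluster 30 was at 1.60 in thinned cells. The direction turned under some setting for 10 of the 23 compared clusters, none among the 6 beyond 2-fold. For 3 of the 10 the reported interval excluded a ratio of 1: cluster 4 was at 0.66 at resolution 2, cluster 5 at 0.94 in thinned cells and 0.90 in deep cells, and cluster 6 at 1.13 with the abundant features left out and 1.27 in deep cells. The other 7 included clusters 22 and 33 (above) and 34, from 0.68 to 2.08 in thinned cells. The log2 ratio of Maker00018099 (-7.69) was -6.32 as mean CPM per cell and -5.98 without the 5% of cells with most UMIs. In 6 of 207 cases no matching cluster was found. The 207 cases include settings that kept the reported clusters, such as the minimum of 1000 UMIs, where a match was certain. Leaving aside settings that changed nothing, 55 values that answer a comparison stayed within their bounds and 32 did not, all given here. Of the other values, 123 stayed, 39 moved and 5 turned direction, namely those of clusters 4, 5 and 6 above. Turned values of clusters whose reported interval held 1 are not among these 5. A minimum of 1000 UMIs and keeping doublet calls changed nothing because no cell was below the minimum and no call was made, so they say nothing about stability. No value under any setting could be had for the gene lists, the list genes' share of cells and the gene in the series title. With 12 and 19 UMIs, the 5 dpa levels of Maker00018099 and DJKW.5991 are limited by depth. No paired analysis was possible because each group has 1 library.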

Other observations

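Of the tests in this part, those on centring and on neighbouring identifiers were written before their results were seen; the others were chosen afterwards. Leading features of a cluster often carried neighbouring identifier numbers. In 12 of the 30 separated clusters at least 2 of the 5 leading features lay within 20 consecutive DJKW numbers, and in 5 clusters at least 3 did. In cluster 18 all 5 lay between 15208 and 15221, and in cluster 11 4 lay between 15213 and 15225; clusters 11 and 18 were matched to 1 common cluster at resolution 0.5 and in thinned cells. Cluster 15 had 4 between 6421 and 6431, and cluster 21 had 3 between 8316 and 8319. One hypothesis is that neighbouring numbers share profiles over cell groups. Over 9058 pairs of consecutive numbers, the median correlation of the profiles over 36 clusters was 0.25, against a highest value of 0.16 in 100 shuffles of the numbers, and 5.13% of pairs had a correlation above 0.8, against at most 0.77% in a shuffle. The median was 0.22 at a distance of 2 and 0.14 at a distance of 5. Whether the numbers follow the genome, and whether such neighbours are tandem copies, parts of 1 gene counted apart or copies that share reads, was not tested because no annotation was used here.

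Some separated clusters lay almost wholly in 1 library and were not compared. Cluster 35 had 47 intact and 0 5 dpa cells, which allows a 5 dpa share of up to 0.0426% (3 cells of 7047), cluster 36 had 0 intact and 26 5 dpa cells, which allows an intact share of up to 0.0375%, and cluster 32 had 104 and 7. Among the clusters without strong leading features, cluster 31 held 3 intact and 119 5 dpa cells, cluster 9 held 73 and 555, cluster 7 held 118 and 621, and cluster 24 held 207 and 23.

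The 2 clusters with larger shares at 5 dpa (17 and 30) and the 2 with the smallest ratios (1 and 19) were weighed together. Clusters drawn along a difference shared by all cells of a library are argued against by centring the values per library before clustering. This left the smaller of the ratios of clusters 17 and 30 at 3.74 and the larger of the ratios of clusters 1 and 19 at 0.29. Centring does not remove a library difference particular to a cell group or to depth, so clusters drawn along such a difference are not excluded. Cluster 30 held UMI-rich cells (a median of 6816.5 UMIs). Doublets of cells of the other clusters as its whole make-up are argued against by 409 features at least 10-fold over other cells. Of these, 391 stood above every other cluster, and the median ratio to the highest other cluster was 2.61. The features were chosen for their level in cluster 30, which favours that outcome, and features it shares with other clusters were not weighed. Doublets as a part of cluster 30 are not excluded. Open are a different yield of cell groups from dissociation of blastemas and intact heads, the sampling of single pools and a true change of cell composition during head regrowth, none of which could be tested with 1 library per group.

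Maker00018099 and DJKW.5991 were nearly without UMIs at 5 dpa. Fewer cells of the clusters that hold them is argued against as the whole cause, since within clusters 33 and 21 the smaller of the 2 drops was -6.21 on the log2 scale. The 5 leading features of cluster 33 had a median log2 ratio of 0.10, and 1 of them, DJKW.10625, stood at 1804 CPM in intact and 1936 CPM in 5 dpa cells. Among the 12 lower features ranked first in the pooled comparison, others had 73.5% to 79.8% of their UMIs in cluster 33 (pooled log2 ratios of -3.33 to -2.90). They were listed because they were lower, so their direction cannot speak for a loss of cells. A loss of some of the cells of cluster 33 was not tested apart and stays open for part of the drop of Maker00018099. In cluster 21 the 5 leading features were all lower at 5 dpa (median log2 ratio -1.80, range -2.02 to -1.14, against -0.31 for all its features). Cluster 21 was not compared in size for this reason, and fewer of the cells that define it stays open for part of the drop of DJKW.5991. Lower depth is argued against too, at equal depth of all kept cells (1000 UMIs) or of those with at least 500 UMIs outside the abundant features (7731 intact and 5897 5 dpa cells). The largest of the 4 ratios of the share with a UMI was 0.10, with intervals that did not overlap. Within cluster 33 alone the intervals for Maker00018099 overlapped at 500 UMIs (23.6% to 54.4% and 4.19% to 26.8%). At 1000 UMIs, 56 of the 72 intact cells with a UMI of Maker00018099 lay outside cluster 33, and 118 of the 164 with one of DJKW.5991 outside cluster 21. In these cells free RNA is not set apart from expression. Open is that few strongly expressing cells, of which 10 held 92.4% of the intact UMIs of Maker00018099 and 70.4% of those of DJKW.5991, were missed in the 5 dpa sample, beside a lower level of both features in regenerating heads, a hypothesis that was not tested.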
